A study of Arabidopsis thaliana with 9 samples.

How the data were processed

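Germinating seeds of Arabidopsis thaliana were measured on a 1-colour expression array. The 9 arrays fall into 3 genotypes with 3 arrays each. Col-0 is the wild-type accession. ARF10 seeds carried a transgene with 3 kb of upstream sequence and 2.3 kb of coding sequence of AUXIN RESPONSE FACTOR10 fused to GFP, and mARF10 seeds carried the same transgene with 4 mutations in the target site of microRNA160. Per the labels, each sample held 3 seed lots. Seeds lay on filter paper with 3 ml of water for 3 days at 4 °C in darkness and then for 22 h at 22 °C in light. The labels call the replicates independent biological ones.

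Per the labels' protocols, total RNA was extracted with phenol and SDS, its integrity was checked by capillary electrophoresis, and 5 µg per sample was amplified and labelled with biotin. The authors' deposited values are log2 signals, 1 per probe set and array. The base of the logarithm and the summary and normalization behind the values are not given in the sources used here. Base 2 was inferred from the range of 3.70 to 14.78, which stays below the 16 bits of a scanner. The array medians lay between 7.06 and 7.11, so the arrays had been brought to a common scale before deposit. No further normalization was applied. Scanner files were not used here, so detection of single probe sets was not assessed.

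The table held 22810 probe sets, of which 64 were control probe sets and were left out. Of the other 22746, those with a mean over the 9 arrays at or above the 30th percentile were tested. That percentile lay at a log2 signal of 5.72, and it left 15922 probe sets in and 6824 out. As the mean is over all arrays, a single genotype of a tested probe set can lie below it. Probe sets were named through the platform annotation, which listed 13513 with 1 gene and 503 with several; the other 8730 non-control probe sets were not in the naming table and stay unnamed here. Of the single-gene probe sets, 13436 matched the gene table of assembly TAIR10.1, which was used for names only. No gene was named from a probe set with several genes. Among tested probe sets 8955 carried 1 named gene, for 8866 genes, and the probe set with the highest mean over all arrays stood for a gene with several. The annotation used here names no probe set for ARF10, ARF16 or ARF17, the targets of microRNA160, so the transgene's own transcript was not analysed here.

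A linear model with 1 mean per genotype was fitted to each probe set over all 9 arrays with limma 3.58.1 in R 4.3.3. The residual degrees of freedom were 6, and moderation added 3.11. Contrasts were mARF10 minus ARF10, mARF10 minus Col-0 and ARF10 minus Col-0, with eBayes moderation, Benjamini-Hochberg adjustment over the 15922 probe sets and a threshold of 0.05. A moderated F-test asked for any difference among the 3 genotypes. All adjusted p-values are from these limma tests and are 2-sided. Error is given as the SD over the 3 arrays of a genotype or as the limma standard error (SE) of a log2 difference. The number of arrays limits the precision.

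Before the data were examined, 21 gene lists with 445 distinct genes were fixed. The annotation named 85 of these genes on the array and 72 were tested. The 6 lists with at least 5 measured genes were late embryogenesis abundant (LEA) genes, seed storage protein and oil body genes, photosynthesis and chlorophyll synthesis, Aux/IAA and GH3 auxin-response genes, cell wall loosening enzymes, and gibberellin metabolism and signalling. They were tested against the other named genes with limma's camera at a preset correlation of 0.01, adjusted over the 6 lists of a comparison. Each test was repeated with camera's estimated correlation. As a different question, fry tested whether the genes of a list moved one way, with no comparison to other genes. The estimated correlation between members of a list was 0.39 for LEA genes, 0.54 for storage genes and 0.95 for photosynthesis genes, far above the preset value, so the preset test gives p-values that are too small for these lists. The other 15 lists were too small to test. For 5 of them no gene was named here: ABA metabolism, ABA signalling, the ARF family, auxin transport and perception, and root tip markers. Any of their genes among the unnamed probe sets were not analysed.

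The genes named in the text follow a rule fixed before the data were examined. For each comparison, these are the 10 largest increases and 10 largest decreases among genes that passed the threshold with every array of one genotype above every array of the other. Where under 5 passed in a direction, the 5 with the smallest unadjusted p are named and said not to pass. From each list up to 4 members with the smallest p are named. How many of those 4 were kept was decided later: 4 where the list was shifted, 2 where it was tested but not shifted, and 1 where it was too small to test.

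Alternatives fixed beforehand were other filters, quantile normalization, median centring, a floor at a log2 signal of 4, a trended and robust eBayes, array weights, fits of only the 2 genotypes compared, the replicate number as a block, a fold threshold of 2, a test without moderation, and leaving out each array. The test without moderation held only the 2 genotypes compared, so it differs from the main fit in its arrays as well. The default estimate of array weights did not converge, so the gene-by-gene estimate was used, a choice made after the data were seen. Covariates for photosynthesis transcripts and for the 3' to 5' difference of the GAPDH control probe sets, and another background for the list test, were also chosen after the data were seen.

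The labels name the same-numbered samples of the 3 genotypes together but do not state that they shared a batch or a day. Deviations of same-numbered arrays from their genotype means correlated at -0.08 to 0.25 for mARF10 and ARF10, at -0.17 to 0.48 for mARF10 and Col-0, and at 0.19 to 0.49 for ARF10 and Col-0. By the rule that every pair must correlate above 0.1, the numbers were taken to pair the samples only for ARF10 and Col-0. With 3 arrays per genotype such a match can also arise by chance, so the pairing is not established. The procedure was tested on simulated data, with 200 of 15922 probe sets changed in each of 20 runs for mARF10 against ARF10. It recovered 58.1% of changes of 0.5 log2 units, 94.4% of changes of 1 and 99.7% of changes of 2, with 5.25% of calls false. Simulated noise was independent between genes, so this does not test the list p-values. It was also normal and as large on each array. Real arrays differed in spread, with estimated weights of 0.23 for Col-0 replicate 2 and 2.32 for mARF10 replicate 3. The shares recovered and false hold for the simulated setting only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.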

Results

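The transcriptomes of germinating seeds of 3 genotypes were compared 22 h after transfer to 22 °C. These were wild-type Col-0, ARF10 seeds with an intact microRNA160 target site in the transgene, and mARF10 seeds with 4 mutations in that site. Whether the mutated transgene escaped microRNA160 in these seeds was not tested. Each genotype had 3 arrays, and values are log2 signals given as mean ± SD (n = 3). Correlations between arrays over the tested probe sets ran from 0.968 to 0.997 within genotypes and from 0.967 to 0.995 between them. Both lowest values were pairs with Col-0 replicate 2, with Col-0 replicate 1 and with mARF10 replicate 3.

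The 1st principal component of the tested probe sets held 43.9% of the variance and set Col-0 replicate 2 (41.3) apart from the other 8 arrays (-17.3 to 5.87). The 2nd held 27.7% and ordered the genotypes, with mARF10 arrays at 13.3 to 18.4, Col-0 arrays at -2.75 to 4.63 and ARF10 arrays at -17.7 to -15.5. On Col-0 replicate 2, photosynthesis genes had a mean log2 signal of 8.28, against 9.79 and 9.49 on the other Col-0 arrays and 9.18 to 9.94 on the transgenic arrays. LEA genes, which encode hydrophilic proteins of the desiccating seed, had a mean of 9.79 there against 8.53 and 9.30 on the other Col-0 arrays. The GAPDH control probe sets differed between their 3' and 5' ends by 0.512 on this array and by 0.256 to 0.424 on the others, while those of actin (1.15 against 0.80 to 1.22) and ubiquitin (0.49 against 0.35 to 0.63) lay within the others.

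**Figure D1:**
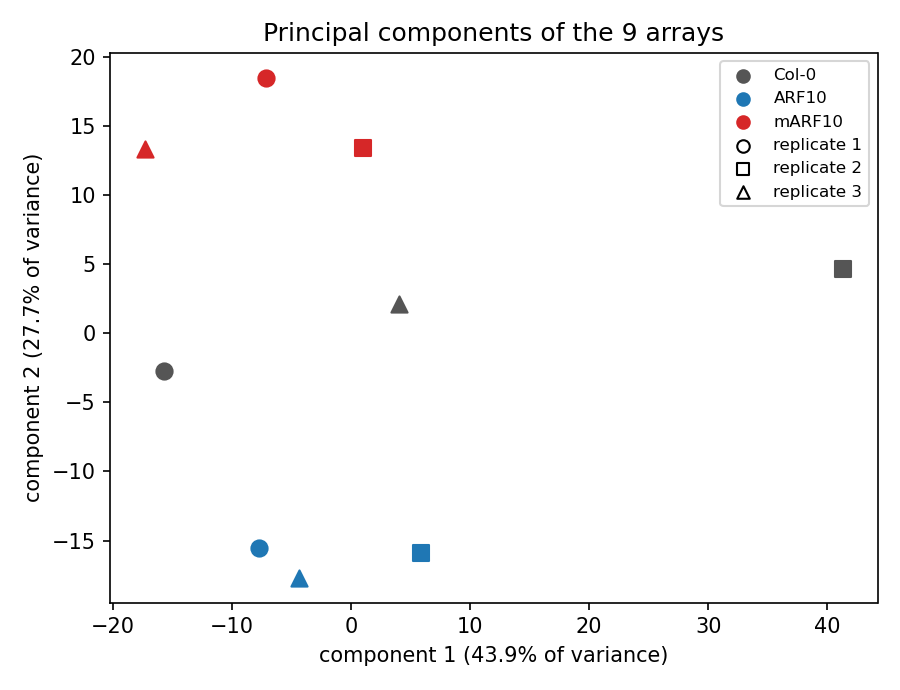
Each point is 1 of the 9 arrays, placed by its score on component 1 (43.9% of variance, horizontal axis) and component 2 (27.7%, vertical axis) of the log2 signals, with colour for genotype and symbol for replicate. Col-0 replicate 2 lies at 41.3 on component 1, and component 2 separates the mARF10 arrays (13.3 to 18.4) from the ARF10 arrays (-17.7 to -15.5).

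The comparison of mARF10 with ARF10 seeds asks what differs when the microRNA160 target site of the transgene is mutated. AT1G47400, which encodes a small peptide of the iron-deficiency response, was at 11.41 ± 0.14 in mARF10 and 7.50 ± 0.45 in ARF10 seeds, a log2 difference of 3.90 (SE 0.45, adjusted p = 0.0143). M17, a LEA gene outside the fixed list, was at 9.65 ± 0.50 against 5.81 ± 0.66, a difference of 3.84 (adjusted p = 0.0317). Its ARF10 mean was close to the filter at 5.72, with 1 array at 5.11 below it, so the size of the difference is uncertain. AT1G47540, of the trypsin inhibitor family, was higher by 3.25 (adjusted p = 0.0052) and AT2G15010, of the thionin family, by 2.46 (adjusted p = 0.0279). AT2G43590, of the chitinase family, was higher by 1.97 (adjusted p = 0.0180).

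Further named genes higher in mARF10 than in ARF10 were AT4G31830 (1.59), AT5G46230 (1.46), AT2G43530 (1.35) and AT5G05250 (1.13), with adjusted p from 0.0283 to 0.0427. The ARF10 mean of AT4G31830 (5.77) was also close to the filter. PYE, which encodes a transcription factor of the iron-deficiency response, was higher by 1.14 (adjusted p = 0.0243). Lower in mARF10 were 8 named genes, by smaller steps. SIR, which encodes sulfite reductase, was at 9.82 ± 0.13 in mARF10 and 10.68 ± 0.10 in ARF10 seeds, a difference of -0.86 (adjusted p = 0.0156). SAPX, which encodes the stromal ascorbate peroxidase, differed by -0.77 (adjusted p = 0.0317), and AT4G20320, of the CTP synthase family, by -0.70 (adjusted p = 0.0094). The subtilase genes AT5G45650 and AT5G59130 differed by -0.66 and -0.64, AT1G80280 by -0.74, and AT3G23940, which encodes a dihydroxyacid dehydratase, by -0.46. GI (GIGANTEA), a gene of the circadian clock and flowering, differed by -0.45 (adjusted p = 0.0425).

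**Figure D2:**
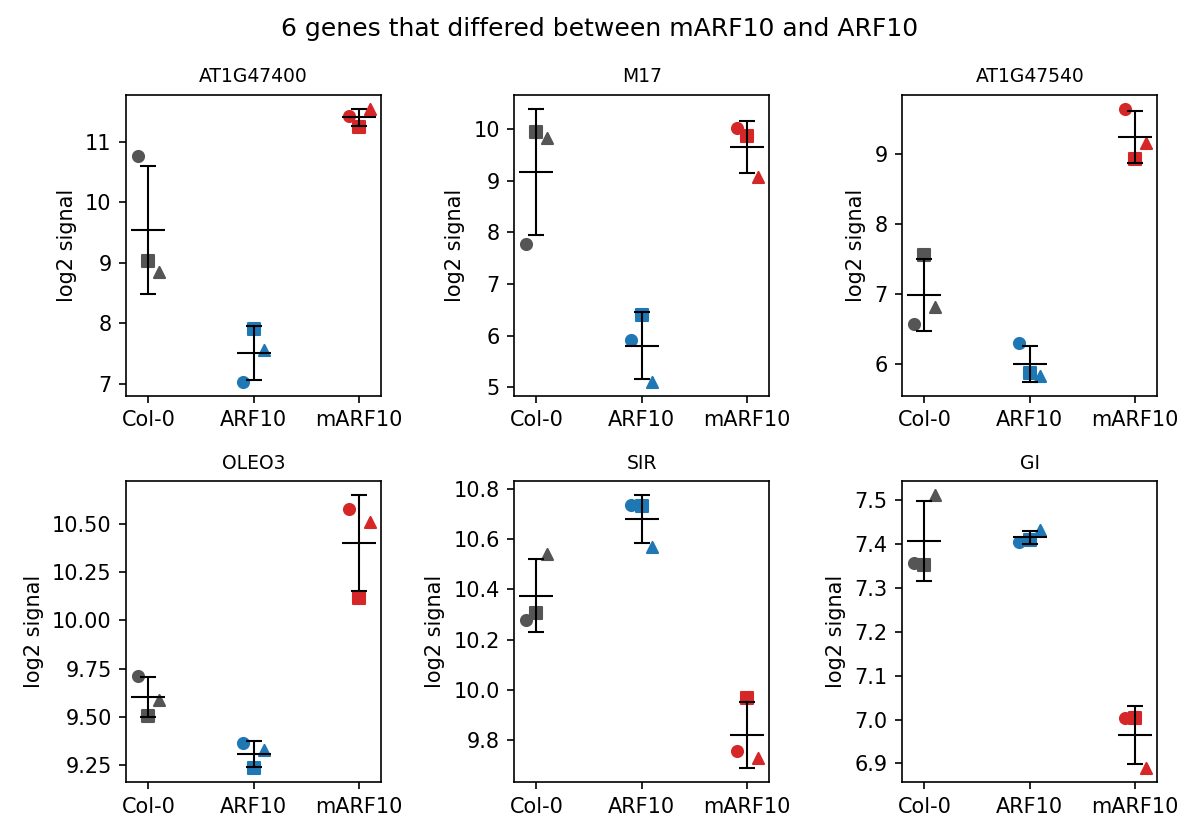
The log2 signal (vertical axes, not starting at 0) of 6 genes called between mARF10 and ARF10 is drawn for each array by genotype, with symbols for replicates, a long bar for the mean and whiskers for the SD (n = 3). In AT1G47400, M17, AT1G47540 and OLEO3 every mARF10 array lies above every ARF10 array, and in SIR and GI every mARF10 array lies below.

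In this comparison 65 of 15922 probe sets passed, 50 higher and 15 lower in mARF10, and 32 of them carried a named gene (24 higher, 8 lower). All 65 had non-overlapping arrays; over all tested probe sets 22.3% did, against 10% by chance. Among the called, 32 were at least 2-fold higher and 1 at least 2-fold lower. The largest differences lay in probe sets unnamed here, at 4.94 and 4.41 upward and -2.03 downward. The unadjusted p was under 0.05 for 1741 probe sets, against 796 by chance. A test without moderation, on the arrays of these 2 genotypes alone, called 0 after adjustment and 2085 unadjusted. The count fell whichever ARF10 or mARF10 array was left out, which also leaves fewer arrays in that genotype. It was 1 without ARF10 replicate 3, 3 without ARF10 replicate 2, 5 without ARF10 replicate 1, 2 without mARF10 replicate 1, 26 without mARF10 replicate 2 and 10 without mARF10 replicate 3. It was 173 without Col-0 replicate 1 and 268 without Col-0 replicate 2, both of which kept all 65, and 51 without Col-0 replicate 3, of which 41 were among the 65, since Col-0 arrays enter the estimate of spread; a fit of the mARF10 and ARF10 arrays alone called 397 and one with array weights 784.

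Seed storage protein and oil body genes were higher in mARF10 than in ARF10 in 5 of 5 measured genes, with a median difference of 1.54 and adjusted p = 8.19e-11 by camera. That call was lost with an estimated correlation (adjusted p = 0.0524 with an estimated correlation). In fry, which tests for a move one way and not against other genes, adjusted p was 0.0054. OLEO3, an oleosin of the oil body, was at 10.40 ± 0.25 against 9.31 ± 0.07, a difference of 1.09 (adjusted p = 0.0120). It was the 1 measured member called over all probe sets, and 5 were called when adjusted over the list alone. The annotation named 7 of the 22 genes in this list, so any members among the unnamed probe sets were not counted. PAP85, of the vicilin storage protein family, differed by 3.34 (SE 0.67, adjusted p = 0.0937), the cupin gene AT2G28490 by 3.04 (SE 0.53, adjusted p = 0.0582) and the oleosin gene AT3G01570 by 1.46 (adjusted p = 0.0697), none passing over all probe sets.

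LEA genes had positive differences in 20 of 21 measured genes, with a median of 0.76 and adjusted p = 1.2e-11 by camera. That call was lost with an estimated correlation (adjusted p = 0.120 with an estimated correlation), and fry's test of no change gave adjusted p = 0.0578. One LEA member passed over all probe sets, AT3G02480, at 13.24 ± 0.17 in mARF10 and 12.27 ± 0.12 in ARF10 (difference 0.97, adjusted p = 0.0243), and 6 passed when adjusted over the list alone. AT3G53040 differed by 1.63 (adjusted p = 0.0941), AT2G03850 by 1.28 (adjusted p = 0.131) and DI21 by 0.36 (adjusted p = 0.184). The arrays of the groups did not overlap in 15 of the 21 LEA genes. Chance gives 10% and all tested probe sets gave 22.3%, and the members of the list correlate, so they do not count as independent. At the preset correlation, whose p-values are too small for these lists, camera made the LEA and storage calls without each array in turn. Of 10 splits of the mARF10 and ARF10 arrays, the real one among them, 6 gave at least 2 shifted lists at that correlation.

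**Figure D3:**
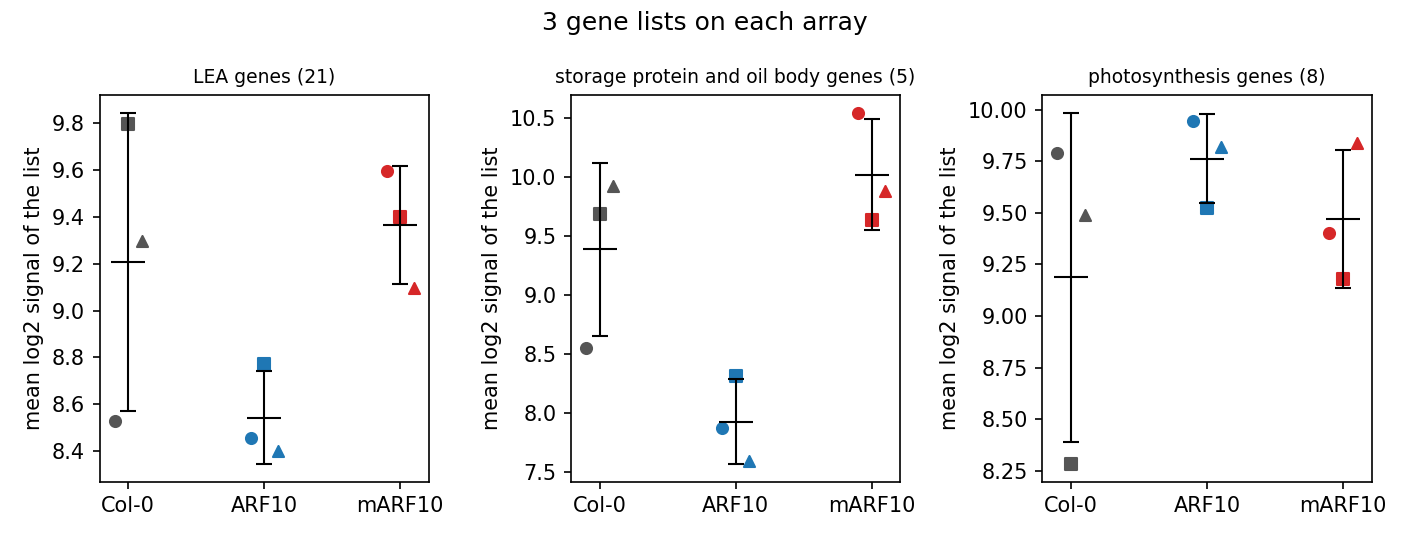
The mean log2 signal of 21 LEA genes, 5 storage protein and oil body genes and 8 photosynthesis genes (vertical axes, not starting at 0) is drawn for each array by genotype, with symbols for replicates, a long bar for the mean and whiskers for the SD (n = 3). Every mARF10 array lies above every ARF10 array for LEA and storage genes, while Col-0 replicate 2 has the lowest photosynthesis mean (8.28) of the 9 arrays.

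The other 4 tested lists gave no call between mARF10 and ARF10, and none of their measured members passed, also when adjusted over each list alone. Photosynthesis genes had a median of -0.36 (6 of 8 negative, adjusted p = 0.227), with LHCB4.1 at -0.54 and PORB at -0.71. At the preset correlation camera called this list lower without Col-0 replicate 2 (adjusted p = 0.0214) and without mARF10 replicate 3 (adjusted p = 0.0212). With all arrays and an estimated correlation, camera gave adjusted p = 0.575. Cell wall loosening enzymes had a median of -0.21 (adjusted p = 0.363), with EXPA4 at 0.33 and EXPA15 at -0.68. For the auxin-response list the median was 0.03, while the mean was -0.09 and the test pointed down (adjusted p = 0.363); WES1 was at -0.27 and GH3.1 at -0.37. For the gibberellin list the median was 0.02, while the mean was -0.06 and the test pointed down (adjusted p = 0.363); SPT was at -0.21 and GID1C at -0.24.

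In lists too small to test, no named and measured member was called between mARF10 and ARF10. Any members among the unnamed probe sets were not counted, and 33 of the 65 called probe sets were unnamed. The measured member with the smallest p was COR47 (0.35) for ABA- and desiccation-responsive genes and BZIP53 (0.07) for seed maturation regulators. It was SDP1 (-0.22) for storage oil mobilisation and SE (-0.15) for the small RNA pathway. For cell cycle genes it was PRL (-0.03), for heat shock AT5G37670 (-0.14), for pathogen and jasmonate response PDF1.2 (-0.08), for seed coat and endosperm markers BAN (-0.08), and for shoot meristem and leaf polarity markers CLV3 (-0.04). Among reference genes AT2G28390 differed by 0.07.

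Comparing mARF10 with Col-0 seeds asks what differs from the wild type. AT1G47540 was at 9.25 ± 0.37 in mARF10 and 6.98 ± 0.52 in Col-0 seeds, a log2 difference of 2.27 that did not pass (adjusted p = 0.107). The multicopper oxidase-like gene sks16 differed by 1.21, AT3G58060, which encodes a metal transporter, by 0.79, OLEO3 by 0.80 and AT1G62510 by 0.54. On the lower side, QQS differed by -1.04, AT4G20320 by -0.51, AT3G23940 by -0.45, GI by -0.44 and AT2G26450 by -0.40. None of these passed, with adjusted p from 0.107 to 0.246, though every mARF10 array was apart from every Col-0 array in each. QQS lay at 5.78 ± 0.06 in mARF10 seeds, close to the filter at 5.72.

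Between mARF10 and Col-0, limma called 0 of 15922 probe sets, with 1697 under an unadjusted p of 0.05 and 796 by chance. The test without moderation, on the arrays of these 2 genotypes alone, called 0, with 879 unadjusted. Arrays did not overlap in 12.4% of probe sets, against 10% by chance. The count was 14 without Col-0 replicate 1, 11 without Col-0 replicate 2, 5 without mARF10 replicate 2 and 1 without Col-0 replicate 3, and 82 with array weights.

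Storage protein and oil body genes were positive in 5 of 5 measured genes between mARF10 and Col-0, with a median of 0.72 and adjusted p = 0.0060 by camera. The call was lost with an estimated correlation (adjusted p = 0.649 with an estimated correlation), without Col-0 replicate 1 (adjusted p = 0.371) and without mARF10 replicate 1 (adjusted p = 0.107). The test of no change in fry gave adjusted p = 0.440. No member passed over all probe sets and 1, OLEO3, passed when adjusted over the list alone. AT3G01570 differed by 0.72, PAP85 by 0.83 (SE 0.67) and AT2G28490 by 0.55 (SE 0.53).

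LEA genes had a median of 0.14 between mARF10 and Col-0 (14 of 21 positive, adjusted p = 0.123), with AT3G02480 at 0.65, the 1 member that passed when adjusted over the list alone, and DI21 at 0.32. At the preset correlation camera called this list higher without Col-0 replicate 2 (adjusted p = 6.65e-07) and without Col-0 replicate 3 (adjusted p = 0.0283). It also did so without mARF10 replicate 3 (adjusted p = 0.0031). With all arrays and an estimated correlation, camera gave adjusted p = 0.767. The LEA median without Col-0 replicate 1 was -0.25. Photosynthesis genes had a median of 0.24 (8 of 8 positive, adjusted p = 0.158), with PSBW at 0.41 and PRK at 0.78. The photosynthesis median was -0.24 without Col-0 replicate 2. At the preset correlation camera called the list higher without Col-0 replicate 1 (adjusted p = 0.0270) and without Col-0 replicate 3 (adjusted p = 0.0289). With all arrays and an estimated correlation, its adjusted p was 0.767.

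The remaining tested lists were not called between mARF10 and Col-0 (adjusted p = 0.734 each). The auxin-response list had a median of 0.02, a mean of -0.06 and a test that pointed down, with GH3.1 at -0.26; its member WES1 (-0.36) passed when adjusted over the list alone. The gibberellin list had a median of 0.03, a mean of -0.02 and a test that pointed down, with GID1B at 0.16; its member GID1C (-0.31) passed when adjusted over the list alone. Cell wall loosening enzymes had a median of 0.05, a mean of -0.05 and a test that pointed up, with EXPA15 at -0.73 and EXPA4 at 0.33. In lists too small to test, SDP1, a lipase gene of storage oil breakdown, differed by -0.24 and passed when adjusted over its list alone. LTI30 differed by -0.28, BZIP53 by 0.18, SE by -0.25, PHV by -0.15, PRL by 0.12, AT5G37670 by 0.10, PDF1.2 by -0.02, BAN by -0.01 and AT2G28390 by 0.09, none passing.

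The comparison of ARF10 with Col-0 seeds asks what the transgene with its intact target site changes. AT2G43590 was at 7.92 ± 0.46 in ARF10 and 9.72 ± 0.26 in Col-0 seeds, a log2 difference of -1.80 that did not pass (adjusted p = 0.248). M17 differed by -3.36 (SE 0.57), QQS by -1.05, AT1G04660 by -0.64 and AT1G62510 by -0.44. On the higher side were the glutathione transferase gene ATGSTF13 (0.57), AT1G72800 (0.55), the thioredoxin gene ty2 (0.37), the antenna protein gene LHCB4.3 (0.33) and AT4G14500 (0.30). None of these passed, with adjusted p from 0.248 to 0.892. In ARF10 seeds QQS (5.76 ± 0.09) and M17 (5.81 ± 0.66) lay close to the filter at 5.72, so the sizes of their differences are uncertain.

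Between ARF10 and Col-0, limma called 0 of 15922 probe sets, with 739 under an unadjusted p of 0.05 against 796 by chance; the test without moderation called 0, with 582 unadjusted. With the replicate number as a block, which treats these samples as paired, limma also called 0. The unadjusted count then rose above chance, to 997 in a fit of these genotypes alone and 1157 over all 9 arrays. Arrays did not overlap in 9.20% of probe sets, against 10% by chance. The count was 19 without Col-0 replicate 1 and 1 without Col-0 replicate 3, and 1 with quantile normalization, with a trended and robust eBayes or with array weights.

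Storage protein and oil body genes were lower in ARF10 than in Col-0 in 5 of 5 measured genes, with a median of -1.27 and adjusted p = 3.91e-08 by camera. With an estimated correlation the call was lost (adjusted p = 0.103 with an estimated correlation), and fry's test of no change gave adjusted p = 0.0766. No member passed over all probe sets, and all 5 passed when adjusted over the list alone. PAP85 differed by -2.51 (7.20 ± 0.59 against 9.71 ± 1.39), AT2G28490 by -2.49, AT2G25890 by -1.27 and AT3G01570 by -0.74.

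LEA genes were negative in 20 of 21 measured genes between ARF10 and Col-0, with a median of -0.70 and adjusted p = 3.76e-10 by camera. With an estimated correlation this call was lost (adjusted p = 0.154 with an estimated correlation), and fry's test of no change gave adjusted p = 0.189. No member passed over all probe sets, and 1, AT3G53040 (-1.49), passed when adjusted over the list alone. The dehydrin gene named LEA differed by -1.58, AT4G39130 by -0.72 (an ARF10 mean of 5.42, below the filter) and AT3G02480 by -0.32. The LEA mean was 8.53, 9.79 and 9.30 on the Col-0 arrays, highest on replicate 2, and 8.40 to 8.77 on the ARF10 arrays.

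Photosynthesis genes were positive in 8 of 8 measured genes between ARF10 and Col-0, with a median of 0.54 and adjusted p = 1.74e-04 by camera. That call was lost with an estimated correlation (adjusted p = 0.313 with an estimated correlation) and without Col-0 replicate 2 (adjusted p = 0.163), the array with the lowest photosynthesis mean. The test of no change in fry gave adjusted p = 0.382. No member passed, also when adjusted over the list alone. LHCB4.1 differed by 0.56, PORB by 1.04, LHCB4.2 by 0.53 and PSBW by 0.42, and the list overlapped between ARF10 and Col-0 arrays in each of its 8 genes.

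Other lists were not called between ARF10 and Col-0. Cell wall loosening enzymes had a median of 0.05 (adjusted p = 0.140), with XTH33 and XTH18 both at 0.54. At the preset correlation camera called them higher without Col-0 replicate 2 (adjusted p = 0.0194). With all arrays and an estimated correlation, camera gave adjusted p = 0.313. The gibberellin list had a median of 0.02 (adjusted p = 0.629), with SPT at 0.17 and GID1B at 0.14, and the auxin-response list a median of 0.05 (adjusted p = 0.792), with WES1 at -0.10 and GH3.1 at 0.11. In lists too small to test, LTI30 differed by -0.82, BZIP53 by 0.10, AIM1 by -0.10, AGO7 by 0.11, PHV by -0.15, PRL by 0.15, AT5G37670 by 0.24, PDF1.2 by 0.07, BAN by 0.07 and the reference gene AT4G34270 by 0.02, none passing.

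Across all 3 genotypes the F-test called 13 probe sets, all of them among the 65, with 1505 under an unadjusted p of 0.05. The 7 that were named were OLEO3, SIR, AT4G20320, AT2G43590, AT1G47400, AT1G47540 and AT1G62510. In 10 of the 13 mARF10 had the highest and ARF10 the lowest mean. AT1G62510 was at 12.07 ± 0.09 in mARF10, 11.53 ± 0.14 in Col-0 and 11.09 ± 0.01 in ARF10. This count was 161 without Col-0 replicate 1, 98 without Col-0 replicate 2, 8 without Col-0 replicate 3, 3 without ARF10 replicate 1, and 0 without ARF10 replicate 2 or ARF10 replicate 3. It was 1 without mARF10 replicate 1, 8 without mARF10 replicate 2 and 1 without mARF10 replicate 3, and 409 with array weights.

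No probe set (0) was called in the same direction in both mARF10 comparisons. At an unadjusted p under 0.05, 742 differed in the same direction in both. The shared mARF10 arrays raise that number, and its value for unchanged groups was not simulated. The count of shared calls was 10 without Col-0 replicate 1, 11 without Col-0 replicate 2 and 5 without mARF10 replicate 2, and 72 with array weights. All 65 probe sets called between mARF10 and ARF10 differed in the same direction from Col-0. Of these, 57 did so at an unadjusted p under 0.05, a number that was not simulated either. Unchanged groups that share the mARF10 arrays gave 91.8% in the same direction on average and 98.5% at most. Col-0 lay between the transgenic genotypes in 64 of the 65 (98.5%, simulated 83.2%, at most 93.8%), at a median of 41.3% of the way from ARF10 to mARF10. Over all tested probe sets the differences of both mARF10 comparisons correlated at 0.67, against 0.50 simulated, with a covariance of 0.0338 against 0.0091. The simulated values already hold the sharing of the mARF10 arrays, but not the deviations that same-numbered ARF10 and Col-0 arrays had in common (correlations of 0.19 to 0.49), which add to the covariance of both comparisons. The excess over the simulated values is therefore no measure of a genotype effect, and genes are not independent replicates.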

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

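The fits with the photosynthesis mean or the GAPDH 3' to 5' difference as a covariate, the other background for the list test and the gene-by-gene array weights were chosen after the data were seen; the other alternatives were fixed beforehand. Of the 20 named genes that passed between mARF10 and ARF10, 20 passed under quantile normalization, median centring, the floor, the trended eBayes, array weights and both covariates, 18 without a filter and 16 with the block; none changed sign. Leaving out an ARF10 or mARF10 array kept 0 to 6 of them, and leaving out Col-0 replicate 3 kept 16. The default array weights did not converge and were not used. Alternatives for the ARF10 transcript itself were not run, as it was not analysed here. Photosynthesis as a covariate gave no list counts, as it is built from a list. Signal over background limits dim probe sets. Without the filter 0 of the 6824 left out were called in each comparison, but the filter does not keep out a dim genotype: 2 of the 65 called probe sets had a genotype mean below it in the comparison, BHLH101 (5.32 in ARF10) among them, and 3 had at least 1 such array. Their log2 differences are uncertain in size. Where no reason is given the cause was not tested.

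For mARF10 against ARF10, calls numbered 65, and 784 with array weights, 397 with only these groups in the fit, 0 without moderation, 33 with at least a 2-fold difference (a stricter rule), 1371 with the photosynthesis covariate, 105 with the GAPDH covariate, and 1 (without ARF10 replicate 3) to 268 (without Col-0 replicate 2) with an array left out. For mARF10 against Col-0 they numbered 0, and 82 with array weights, 90 with the photosynthesis covariate and 0 to 14 (without Col-0 replicate 1) with an array left out. For ARF10 against Col-0 they numbered 0, and 1 with quantile normalization, 1 with the trended eBayes, 1 with array weights, 14 with the photosynthesis covariate and 0 to 19 (without Col-0 replicate 1). The F-test gave 13, and 6 without a filter, 409 with array weights, 846 and 33 with the photosynthesis and GAPDH covariates and 0 (without ARF10 replicate 2 or ARF10 replicate 3) to 161 (without Col-0 replicate 1). Calls shared by both mARF10 comparisons numbered 0, and 72 with array weights, 85 with the photosynthesis covariate and 0 to 11 (without Col-0 replicate 2).

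Shifted lists numbered 2, 1 and 3 for mARF10 against ARF10, mARF10 against Col-0 and ARF10 against Col-0. With an estimated correlation they numbered 0, 0 and 0. By fry, which asks whether a list moved and not whether it moved more than other genes, they numbered 1, 0 and 0. For mARF10 against Col-0 they numbered 2 with the filter at the 50th percentile, 0 with array weights, 2 with the GAPDH covariate and 0 (without mARF10 replicate 1) to 3 (without Col-0 replicate 3).

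With the replicate number as a block, calls numbered 70 for mARF10 against ARF10, of which 50 were among the 65, and 17 for the F-test, with 0 and 0 for the comparisons with Col-0, 0 shared and 2, 1 and 3 lists. In ARF10 against Col-0 the numbers were taken as pairs by the correlation rule, and 6 of 6 arrays correlated best with their own number. There the block changed no call, though it raised the unadjusted count from 739 to 1157 (997 with only these groups in the fit). For mARF10 against ARF10 2 of 6 arrays correlated best with their own number, and for mARF10 against Col-0 3 of 6. In those comparisons the rule found no pairs.

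Signs turned in genes and list medians that had not passed, most of them near 0. Between mARF10 and ARF10, PRL was 0.057 with array weights, 0.110 with the photosynthesis and 0.013 with the GAPDH covariate, and ran from -0.116 to 0.139 with an array left out. Likewise CLV3 ran from -0.206 to 0.078, BAN from -0.147 to 0.022, the auxin-response median from -0.017 to 0.053 and the gibberellin median from -0.091 to 0.060, with the latter -0.015 under array weights.

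Between mARF10 and Col-0, BAN was 0.0013 under quantile normalization, 0.0053 under median centring and 0.011 with the photosynthesis covariate, and ran from -0.058 to 0.089 with an array left out. PRL was -0.013 with the photosynthesis and -0.023 with the GAPDH covariate (-0.071 to 0.332 with an array left out), and PDF1.2 was 0.0025 and 0.023 (-0.121 to 0.063). The cell wall median was -0.072 under array weights (-0.119 to 0.129). With an array left out GID1B ran from -0.0041 to 0.279, LTI30 from -0.681 to 0.286, AT2G28490 from -0.041 to 0.998, AT5G37670 from -0.014 to 0.156, the auxin-response median from -0.0014 to 0.027 and the gibberellin median from -0.038 to 0.046. The LEA median ran from -0.254 (without Col-0 replicate 1) to 0.421 (without Col-0 replicate 2), and the photosynthesis median from -0.241 (without Col-0 replicate 2) to 0.565 (without Col-0 replicate 1).

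Between ARF10 and Col-0, PRL was -0.123 with the photosynthesis and -0.036 with the GAPDH covariate (-0.041 to 0.362 with an array left out), GID1B was -0.016 with the photosynthesis covariate (-0.023 to 0.260), AT4G34270 was -0.0043 with it (-0.012 to 0.074), and AGO7 was -0.031 with array weights. The auxin-response median was -0.012 without a filter and -0.010 with the photosynthesis covariate (-0.032 to 0.070), and the gibberellin median was -0.023 with array weights and -0.015 with the photosynthesis covariate (-0.050 to 0.076). GH3.1 ran from -0.038 to 0.189.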

Other observations

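The tests of Col-0 replicate 2 were chosen only after its position was seen, and so was the test of iron-deficiency genes against LEA and storage genes from array to array. The tests of the LEA and storage genes, of the wider iron-deficiency set and of other splits of the arrays were written down before their results were seen.

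The mean of the LEA and storage genes, 26 genes from lists that camera had called, was higher in mARF10 than in ARF10 arrays by 1.06 (95% interval 0.22 to 1.90), though both calls were lost with an estimated correlation (adjusted p = 0.120 and 0.0524), fry's test of LEA genes missed the threshold (0.0578) and 2 of the 26 passed singly. Seeds less advanced in germination may hold more of these transcripts. With the photosynthesis mean of each array as a covariate, a stand-in for germination progress, the difference stayed at 0.88 (0.27 to 1.48). That mean was 9.18 to 9.84 on mARF10 and 9.52 to 9.94 on ARF10 arrays. With such overlapping values the covariate could hardly have removed the difference, so germination progress as a cause is not decided. With the GAPDH 3' to 5' difference as a covariate, the difference in the LEA and storage mean stayed at 1.03 (0.16 to 1.90). The GAPDH value was 0.27 to 0.41 on mARF10 and 0.26 to 0.42 on ARF10 arrays. RNA integrity as GAPDH measures it was thus alike in both genotypes, and the covariate could hardly change the result. Integrity by other measures was not tested as a cause. Effects of the transgene, of its insertion site and of the parent plants that made the seed lots stay open and untested. A delay in germination stays open too, also one that photosynthesis transcripts do not follow.

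Some genes called higher in mARF10 than in ARF10 have known roles in the iron-deficiency response: AT1G47400, PYE, AT5G05250, BHLH101 (1.06, with an ARF10 mean of 5.32, below the filter) and AT3G58060 (0.77). They were noticed among the calls and belong to no list fixed beforehand, so that 5 of 9 measured genes of a list drawn up afterwards were called is no test of a shift in this response. A wider response could have moved the other 4, but their median difference was 0.012, with 2 of 4 higher, and a list that leaves out the called genes excludes nothing. Any iron-deficiency genes among the unnamed probe sets were not counted, and 33 of the 65 called probe sets were unnamed. The called iron-deficiency genes may have followed the LEA and storage genes; their deviations within genotypes correlated at -0.30 over the 9 arrays (Spearman -0.20, exact permutation p = 0.736 over 216 rearrangements), which decides neither way with so few arrays. Whether the response as a whole differed stays open.

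Col-0 replicate 2 lay apart from the other 8 arrays. Its photosynthesis mean was 1.21 below the lower of the other Col-0 arrays, which were 0.30 apart, but its LEA mean was 0.49 above the higher of them, within their gap of 0.77, so whether this sample may have been less advanced in germination cannot be told. Its GAPDH 3' to 5' difference of 0.512 was the highest of the 9 arrays, but those of actin (1.15, others 0.80 to 1.22) and ubiquitin (0.49, others 0.35 to 0.63) lay within the others, and over the other 8 arrays the GAPDH difference and component 1 correlated at 0.39, so whether its RNA was less intact is not settled. Each array was also placed on the 65 probe sets that best parted ARF10 from mARF10 without it. Col-0 replicate 2 lay 44.6% of the way and the other Col-0 arrays at 41.6% and 29.7%. ARF10 arrays lay at 1.67% to 12.7% and mARF10 arrays at 72.3% to 106%. Col-0 replicate 2 lay above the ARF10 range by more than that range is wide, which argues against an ARF10 sample. It lay below the mARF10 range, but by less than that range is wide, so a mislabelled mARF10 sample is not excluded. A biological difference between Col-0 seed lots was not tested.

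Other splits of the arrays were counted for each result. For mARF10 against ARF10, 1 of 10 splits gave 65 calls, the real one, with a highest other count of 0; 6 of 10 gave at least 2 shifted lists, with a highest other count of 3. For mARF10 against Col-0, 10 of 10 splits gave at least 0 calls, as any split must (highest other 0), and 9 of 10 gave at least 1 shifted list (highest other 3). For ARF10 against Col-0 these were 10 of 10 (highest other 0) and 4 of 10 at 3 lists (highest other 3). The splits of 3 against 3 arrays are too few for a share under 0.05. Of 100 splits drawn from 280 for the F-test, 1 gave 13 calls, the real one, and the highest other gave 2. As many calls were thus rare among the drawn splits, a share under 0.05. The splits mixed all arrays freely, though deviations of same-numbered ARF10 and Col-0 arrays correlated. The real count also fell to 0 without ARF10 replicate 2 or ARF10 replicate 3, so this share does not exclude chance. For the overlap of 0, all 100 gave as many, as any split must (highest other 0), so that count tests nothing.

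Other named genes called higher in mARF10 than in ARF10, picked after their values were seen, were EEL, which encodes a bZIP transcription factor (1.02), the histone H2B gene HTB2 (0.63), the glutaredoxin gene GRXC1 (0.85) and the plantacyanin gene ARPN (0.96).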
